A study of Staphylococcus aureus with 25 samples.

How the data were processed

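RNA was measured by sequencing in 25 libraries of a clinical methicillin-resistant strain (MRSA) of Staphylococcus aureus. Per the labels' protocols, bacteria were grown with shaking at 37 °C in tryptic soy broth. They were then kept without fibres (Control), with uncoated cellulose fibres (Cellulose), or with fibres coated with AGXX, with GOX or with both (GOX_AGXX). AGXX is an antimicrobial coating of silver and ruthenium. The labels do not spell out GOX. Cells were lysed with glass beads, total RNA was taken up by phenol and chloroform extraction, and BGI made the Illumina libraries. Each of the 5 treatments had 1 library at each of 5 times (0, 30, 60, 120 and 180 min), so there were no replicates. The series notes give 26 samples, and 25 were given here. The labels do not say whether 0 min lies before or after the fibres were added.

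The deposited values were raw counts of reads per gene. Per the file headers, the authors counted with featureCounts 1.6.3 on annotation ASM2514v1, by gene feature and locus tag, without regard to strand, and a read that mapped to several places was counted at each of them. Alignment was by Bowtie2, per the submitters' processing notes; its version was not given in the sources used here. Reads from near-identical genes therefore could not be told apart, and neither could reads from the 2 strands. Of the 2731 genes, 671 overlapped another gene and 28 overlapped a gene on the other strand. None of the genes named in the report was among the 28. The 2650 genes other than rRNA, tRNA and tmRNA all had lengths divisible by 3, so lengths are coding lengths. Coordinates are those of the deposited counts, on annotation ASM2514v1.

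The files pair no gene names with the locus tags. The reference table given, made for assembly ASM1342v1 of another strain, has 2872 genes, and 0 of the locus tags matched it. Genes are therefore given by locus tag, with at most 2 that rose and 2 that fell in a comparison, and nothing is said of their function. The 42 gene lists fixed before the data were examined matched 0 genes and could not be tested. In their place, chosen after the files were seen, genes on 1 strand with gaps of at most 100 bp were joined into regions, and the 133 regions with at least 4 tested genes were used as lists.

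Counts of 17 rRNA and 63 tRNA genes were left out of the tests and library sizes, and the tmRNA gene was kept. The main test, edgeR 4.0.16 in R 4.3.3, was the quasi-likelihood test on counts with TMM scaling and the filterByExpr filter. It used the 20 libraries at 30 to 180 min, with treatment and time as terms and 12 residual degrees of freedom. Its error is the spread of treatment effects over the 4 times, pooled over all treatments. A p-value thus sets a difference against that pooled spread, which libraries of treatments outside the comparison also enter. It does not measure the spread between independent cultures. Genes with a Benjamini-Hochberg adjusted p (FDR) under 0.05 were called. The 8 pairwise comparisons share libraries, so their values are not independent. The factorial interaction GOX_AGXX - AGXX - GOX + Cellulose used the same fit. The early against late test added a term for each treatment after 60 min and had 8 residual degrees of freedom. The contrast of 180 with 0 min used the 10 Control and Cellulose libraries, with 4 residual degrees of freedom. The 0 min libraries entered no treatment comparison in the main test, and their log2 differences are given beside the treatment effects. The square root of the common dispersion was 0.275. Values per library are CPM, the counts scaled to library size, after TMM scaling; log2 values per library used a prior count of 2. SD and n refer to the 4 times. Regions were tested with camera (limma 3.58.1) with a correlation between genes preset to 0.01 and again with the estimated correlation, and with fry.

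The named-gene rule, fixed before the data were examined, took the 8 genes with a symbol that rose most and the 8 that fell most among those with FDR under 0.05, the same direction at 4 of 4 times and a mean of at least 20 CPM, and up to 3 members of each gene list. With no symbols and no matched list, it was applied to locus tags and to at most 2 genes in each direction. The tmRNA gene, the pair SA2981_2494 and SA2981_2495, the genes of the early against late and time tests, and the regions were chosen after values were seen.

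RPKM values, reads per kb of coding length scaled to a library's counts without rRNA and tRNA, were computed from the deposited counts. The floor of a library is the 5th percentile of this measure over the 2650 genes. Total counts ran from 15279846 to 25924567 per library. Shares of counts have 95% Wilson intervals, which cover counting error only. Libraries were compared in pairs with a chi-square test over 2508 genes with a mean count of at least 100. Relations across libraries were tested two-sided with 100000 permutations.

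The test steps were checked on simulated counts with 200 changed genes. Each gene was drawn independently of the others, with the common dispersion, the same mean in all libraries apart from the change, and no time effect. The shares recovered hold for that simpler setting. For AGXX vs Control, over 2620 genes, 10.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 6 false calls. DESeq2 recovered 11.9%, 56.7% and 100%, with 15 false calls. An unchanged GOX vs Control comparison gave 0 calls. For the factorial interaction the shares were 0%, 14.9% and 97.0%, with 3 false calls. For the early vs late AGXX vs Control test, over 2623 genes, they were 0%, 4.48% and 53.0%. For 180 min vs 0 min without coating, over 2616 genes, they were 8.96%, 40.3% and 100%, with 4 false calls. Of 10 regions raised 1.5-fold, 10 were called with the preset correlation, beside 1 other, and 5 with the estimated correlation. Simulated genes of a region were uncorrelated, so this check cannot show how often the preset correlation gives false calls for adjoining genes that vary together.

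Alternatives fixed before the data were examined were RLE scaling, total counts only, no low-count filter, the DESeq2 1.42.0 Wald test, rRNA and tRNA kept, only the libraries of the compared treatments, no time term, the effect less the difference at 0 min, all 25 libraries for the time effect, a prior count of 0.5, fry, the estimated correlation, and leaving out each time. Alternatives chosen after the data were seen were the floor subtracted from the counts, the log2 floor as a covariate, genes of at least 100 RPKM, tmRNA left out, no GOX and GOX_AGXX libraries at 180 min, regions with gaps of at most 50 bp, and leaving out each library in turn. The setting with genes of at least 100 RPKM scaled libraries on those genes alone, which recentres their changes. The floor comes from the same counts and differs between treatments. As a covariate it can therefore take up a treatment difference of any cause.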

Results

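The data comprised 25 libraries of a methicillin-resistant strain of Staphylococcus aureus, 1 for each of 5 treatments at each of 5 times. Control cultures had no fibres, Cellulose cultures had uncoated fibres, and AGXX, GOX and GOX_AGXX cultures had coated fibres. Total counts ran from 15279846 (Control at 180 min) to 25924567 (AGXX at 30 min). Among the counted reads, the gene with the most was that of tmRNA (transfer-messenger RNA, which rescues stalled ribosomes), SA2981_tmRNA01 at 841267 to 841627 on the plus strand. It took between 10.98% of counts (GOX_AGXX at 0 min, 95% Wilson interval 10.97% to 10.996%) and 33.2% (GOX_AGXX at 120 min, 33.1% to 33.2%). Genes of rRNA took between 0.217% (Control at 120 min) and 2.57% (GOX_AGXX at 180 min). Of the 300 pairs of libraries, 0 held identical counts, and the smallest chi-square per degree of freedom was 44.3 (AGXX and GOX_AGXX at 120 min).

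Counts of weakly expressed genes differed between libraries. The floor, the RPKM value below which the lowest 5% of the 2650 genes lay, was 5.92 in Control at 0 min and between 1.70 and 2.59 at the 4 later times. In Cellulose libraries it was 17.1 at 0 min and 13.6, 12.1, 19.3 and 20.5 at 30, 60, 120 and 180 min, above Control at each of the 5 times. With AGXX it was 13.1 at 0 min and 4.34, 3.96, 7.19 and 6.30 afterwards. With GOX it was 23.1 at 0 min, 3.23, 2.46 and 3.16 at 30, 60 and 120 min, and 30.9 at 180 min. With GOX_AGXX it was 8.79 at 0 min, 2.65, 3.32 and 4.68 at 30, 60 and 120 min, and 44.3 at 180 min. The first principal component of log2 CPM held 54.0% of the variance and PC2 held 15.5%. Of 4 relations tested over the 25 libraries with two-sided permutation tests, log2 floor followed the first component with a Pearson r of 0.957 and a Spearman rho of 0.953 (both p = 1e-05, the smallest the permutations can give; adjusted p = 2.67e-05). Floor and component were computed from the same counts, weakly expressed genes included, and the sign of the component was set to follow the floor. Part of their relation is therefore built in, and its p does not measure a link between independent quantities. Log2 floor followed the rRNA share with r of 0.778 and rho of 0.747 (permutation p = 1e-05 and 5e-05, adjusted p = 2.67e-05 and 1e-04). Without GOX and GOX_AGXX at 180 min these r values were 0.938 and 0.661. For total counts r was 0.298 and rho 0.347 (permutation p = 0.147 and 0.0896; adjusted p = 0.196 and 0.143), with r of 0.347 without those libraries. For the tmRNA share r was -0.00938 and rho 0.0877 (permutation p = 0.965 and 0.676; adjusted p = 0.965 and 0.772), with r of -0.121 without them. The relation within a single treatment or time, with 5 libraries each, was not tested. The labels do not say whether libraries of a treatment came from 1 culture, so they may not be independent.

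**Figure D1:**
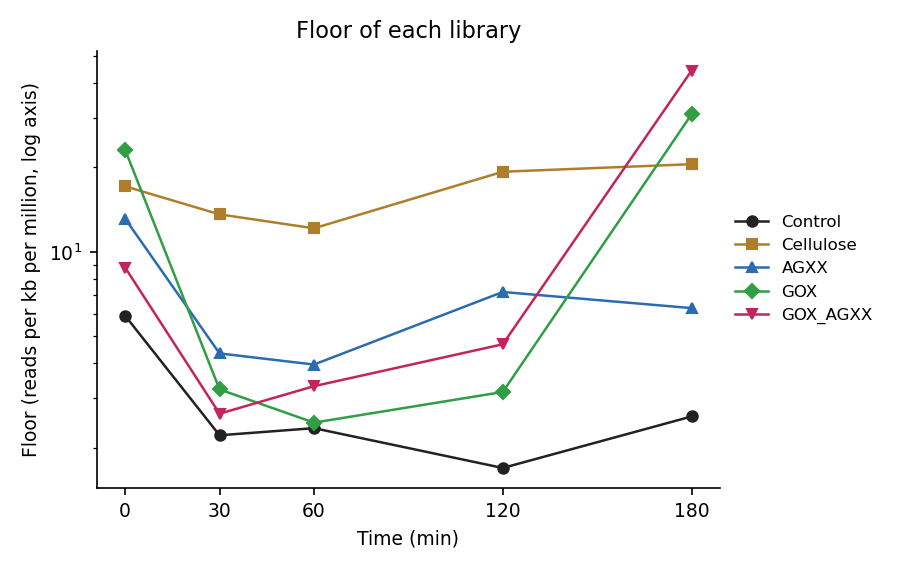
Floor of each library (5th percentile of RPKM over 2650 genes, log axis) against time in minutes, with 1 line per treatment and 1 library per point. Cellulose libraries sit between 12.1 and 20.5 and Control libraries between 1.70 and 5.92, while GOX and GOX_AGXX reach 30.9 and 44.3 at 180 min.

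Cellulose vs Control asked what the uncoated carrier did. In the main fit more of the weakly expressed genes rose than fell with uncoated fibres, and more of the strongly expressed genes fell than rose. Among the 265 genes with the lowest mean RPKM, 178 of 234 tested genes rose and 2 fell, with a median fitted log2 fold change of 1.96. Among the 265 genes with the highest mean RPKM, 1 rose and 105 fell, with a median of -0.50. SA2981_0234 (271348 to 272853, minus strand) rose by 2.98 on the log2 scale (SE 0.46, edgeR FDR = 0.00141), from 11.3 ± 18.3 to 39.8 ± 29.7 CPM (SD over 4 times), and SA2981_0398 (440659 to 441729, plus strand) rose by 2.65 (SE 0.61, edgeR FDR = 0.00409), from 5.65 ± 2.25 to 36.2 ± 17.9 CPM. Both were weakly expressed, at mean RPKM of 18.3 and 24.0, close to the floor of the Cellulose libraries. SA2981_1317 (1402645 to 1402833, minus strand) fell by 2.06 (SE 0.36, edgeR FDR = 0.00175), from 1139 ± 757 to 270 ± 78.9 CPM, and SA2981_1583 (1691889 to 1692071, minus strand) fell by 2.01 (SE 0.46, edgeR FDR = 0.00401), from 3286 ± 2922 to 753 ± 210 CPM. These 4 genes already differed at 0 min, by 1.91, 1.78, -1.54 and -2.59. The tmRNA gene had a fitted log2 difference of -0.30 (SE 0.39, edgeR FDR = 0.547), which was 0.17 with total counts only.

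Of 2620 genes tested in Cellulose vs Control, 1172 were called by edgeR, 462 higher and 710 lower, of which 361 and 91 changed at least 2-fold. Among the called genes 1108 had the same direction at 4 of 4 times, which the test itself favours. Over all genes the share was 57.2%, where independent times would give 12.5%. The times of a treatment may come from 1 culture, and a constant offset between libraries would also raise this share. The share therefore does not by itself show an effect of the fibres. With total counts only, 672 genes were higher and 89 lower, as that scaling moved the median of all genes from -0.17 to 0.28. The call count was 0 without 120 min, 610 without 30 min and 749 without Cellulose at 120 min. The 4 named genes were not called without 120 min (edgeR adjusted p = 0.0554, 0.0561, 0.0554 and 0.0758). With log2 floor as a covariate they were at 1.65, -0.15, -0.71 and -0.12, and less the 0 min difference at 1.12, 0.93, -0.47 and 0.63, with 0 of them called. SA2981_0398 at -0.15 (SE 0.39) and SA2981_1583 at 0.63 (SE 0.99) changed sign, each less than 1 SE from no change. SA2981_0234 was at 5.84 with the floor subtracted, still called, and at 1.82 with no time term, where it and SA2981_0398 were not called (edgeR adjusted p = 0.335 and 0.0666). The call count was 244 with the floor subtracted and 208 with no time term. Among genes of at least 100 RPKM it was 103, 54 higher and 49 lower. That setting scales libraries on those genes alone, which recentres their changes, so it cannot test the excess of falls. The count was 0 both with log2 floor as a covariate and after the 0 min difference was taken off. At the 4 times the floor was 12.1 to 20.5 with Cellulose and 1.70 to 2.59 in Control. The covariate can therefore take up a difference between these treatments whatever its cause.

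**Figure D2:**
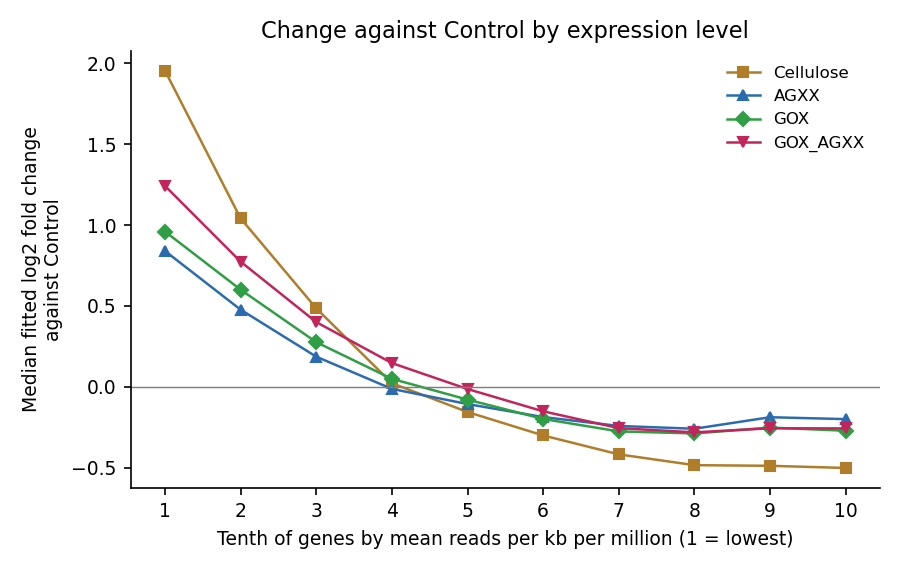
Median fitted log2 fold change against Control (vertical axis) in 10 groups of 265 genes ordered by mean RPKM (horizontal axis, lowest first), with 1 line per treatment. With uncoated fibres the median runs from 1.96 in the lowest group to -0.50 in the highest; with AGXX, GOX and GOX_AGXX it runs from 0.84, 0.96 and 1.24 to -0.20, -0.27 and -0.26.

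In regions of adjoining genes, Cellulose vs Control gave rises in weakly expressed regions. All 9 genes at 127897 to 139114 (plus strand, mean RPKM 15.4) rose, with a median log2 fold change of 2.22, and 8 of 9 genes at 2784018 to 2790943 (minus strand, mean RPKM 18.7) rose, with a median of 2.15. The medians at 0 min were 1.74 and 1.81. All 4 genes at 462291 to 465074 (plus strand) fell, with a median of -0.81, and all 6 genes at 2175118 to 2180463 (minus strand) fell, with a median of -0.49; the medians at 0 min were -0.71 and -0.47. With log2 floor as a covariate the medians of the first 2 regions were both -0.14 with 0 genes called, and with total counts only those of the last 2 were -0.33 and -0.04, with 1 and 0 genes called. After the 0 min difference was taken off, the medians were 0.89, 0.45, -0.01 and 0.0748 in the 4 regions in the order given, with 0 genes called in each, and with the floor subtracted 3, 2, 2 and 0 genes were called. Without 120 min, 0 genes were called in these 4 regions. At 2784018 to 2790943, 5 genes rose without 30 min and 4 without 60 min. At 2175118 to 2180463, 1, 2 and 3 genes fell without 30, 60 and 180 min, and 3 without Control at 180 min.

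AGXX vs Control asked what AGXX-coated fibres did to cultures. In a minus-strand region at 2057231 to 2064700, 9 of 11 genes rose, with a median log2 fold change of 1.19. The median difference was 1.81, 1.01, 0.17 and 1.87 at 30, 60, 120 and 180 min and -0.86 at 0 min. The mean log2 CPM of the region at these 4 times was 6.99, 6.17, 5.80 and 6.48 with AGXX and 5.21, 5.16, 5.67 and 4.54 in Control. With uncoated fibres it was 5.59, 5.91, 5.27 and 5.65, above Control except at 120 min. Part of the rise with AGXX at 30, 60 and 180 min was thus shared with uncoated fibres. SA2981_1908 (2044031 to 2044165, minus strand) rose by 2.04 (SE 0.46, edgeR FDR = 0.00983), from 2749 ± 2921 to 9299 ± 3594 CPM (SD over 4 times), with a 0 min difference of -0.22. SA2981_0991 (1045748 to 1046104, minus strand) rose by 1.84 (SE 0.25, edgeR FDR = 0.00256), from 9.76 ± 3.47 to 34.1 ± 4.85 CPM, against -0.77 at 0 min. SA2981_1583 fell by 2.07 (SE 0.46, edgeR FDR = 0.00948) to 689 ± 102 CPM, and SA2981_1138 (1192261 to 1192662, plus strand) fell by 1.82 (SE 0.42, edgeR FDR = 0.0104), from 886 ± 443 to 301 ± 167 CPM; their 0 min differences were -1.87 and -0.84. With uncoated fibres SA2981_1908 was at 5738, 9197, 5036 and 7026 CPM at 30, 60, 120 and 180 min. SA2981_0991 was then at 19.3, 30.0, 20.3 and 20.2 CPM, and SA2981_1138 at 332, 323.5, 308 and 203. Each lay on the same side of Control as with AGXX at each of these times, as did SA2981_1583. These shifts were thus not particular to AGXX. All 4 genes at 462291 to 465074 fell, with a median of -0.89 and of -0.49 at 0 min. The tmRNA gene had a fitted log2 difference of 0.27 (SE 0.39, edgeR FDR = 0.633). Among the 265 genes with the lowest mean RPKM, 11 of 234 tested rose and 2 fell, with a median of 0.84, and the floor was above that of Control at each time.

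Of 2620 genes tested in AGXX vs Control, 485 were called by edgeR, 152 higher and 333 lower, of which 73 and 68 changed at least 2-fold. Of the 485, 437 had the same direction at 4 of 4 times, which the test itself favours. Over all genes the share was 42.6%, where independent times would give 12.5%, with the same limit as for Cellulose. With total counts only, 181 were higher and 133 lower. The count was 5 without 30 min, 261 without 60 min, 50 without 120 min and 777 without 180 min. It was 153 without AGXX at 30 min, 218 without AGXX at 120 min, 286 without Control at 30 min and 298 without Control at 180 min. SA2981_1908, SA2981_1583 and SA2981_1138 were not called without 30 min (edgeR adjusted p = 0.0747, 0.0633 and 0.0659) or without 120 min (0.0781, 0.111 and 0.118), while SA2981_0991 was called in each of 24 such fits. In the 11-gene region 0 genes rose without 30 min, 4 without 60 min, 2 without AGXX at 30 min, and 5 each without Control at 30 or at 180 min. At 462291 to 465074, 0 genes fell without 30 min and 2 without 120 min. After the 0 min difference was taken off, 0 genes were called by edgeR, and the medians of these regions were 1.83 and -0.45; SA2981_1908, SA2981_0991, SA2981_1583 and SA2981_1138 were at 2.31, 2.66, -0.17 and -0.95. With log2 floor as a covariate SA2981_1583 was at -1.21, still called, and SA2981_1138 at -1.01, not called (edgeR adjusted p = 0.0761). With no time term SA2981_1908, SA2981_1583 and SA2981_1138 were not called (0.101, 0.0561 and 0.160). With only the libraries of both treatments 266 genes were called, 41 with no time term, and 972 without GOX and GOX_AGXX at 180 min.

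**Figure D3:**
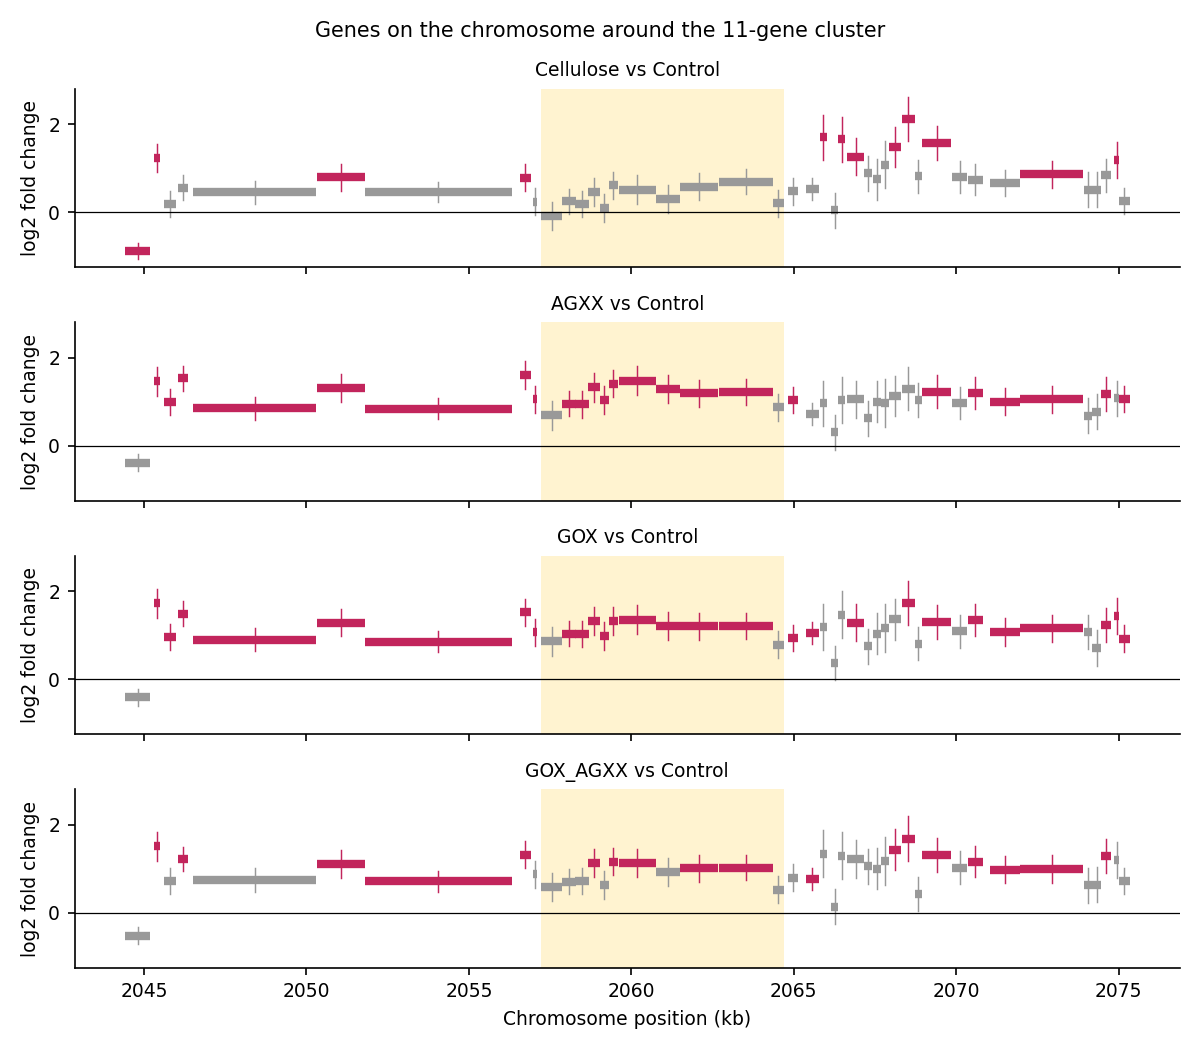
Fitted log2 fold change with SE bars for genes at 2044 to 2076 kb of the chromosome (horizontal axis), 1 panel per treatment against Control; crimson points have FDR under 0.05, grey points do not, and the yellow band marks the 11-gene region. With AGXX, GOX and GOX_AGXX, 9, 9 and 5 genes of the band rose. With uncoated fibres 0 passed, though the mean log2 CPM of the band lay above Control at 30, 60 and 180 min. Over all 42 genes shown, 24, 28 and 18 rose with AGXX, GOX and GOX_AGXX, so the rises extended beyond the band. With uncoated fibres 11 of the 42 rose and 1 fell.

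GOX vs Control asked the same of GOX-coated fibres. In the 11-gene region at 2057231 to 2064700 there were 9 rises, with a median of 1.199; the median difference was 2.09, 0.75, 0.31 and 1.74 at the 4 times and -0.65 at 0 min. SA2981_1908 rose by 2.39 (SE 0.47, edgeR FDR = 0.0130) to 10916 ± 3897 CPM (SD over 4 times), with a 0 min difference of 0.15. SA2981_1893 (2033776 to 2033952, minus strand) rose by 2.24 (SE 0.34, edgeR FDR = 0.00496), from 7.82 ± 6.65 to 31.2 ± 3.56 CPM, against 0.42 at 0 min. SA2981_1131 (1187220 to 1187354, plus strand) fell by 1.68 (SE 0.43, edgeR FDR = 0.0207), from 3526 ± 1999 to 1337 ± 1013 CPM, and SA2981_2502 (2656595 to 2657092, minus strand) fell by 1.47 (SE 0.36, edgeR FDR = 0.0174), from 151 ± 78.3 to 56.8 ± 22.3 CPM. Their 0 min differences were -0.53 and -0.46. With uncoated fibres SA2981_1893 was at 21.2, 27.55, 13.1 and 15.7 CPM at 30, 60, 120 and 180 min. SA2981_1131 was then at 350, 2083, 969 and 955 CPM, and SA2981_2502 at 53.5, 65.7, 113 and 67.2. Each lay on the same side of Control as with GOX at each of these times, as did SA2981_1908. These shifts were thus not particular to GOX. At 462291 to 465074, 3 of 4 genes fell, with a median of -0.60 and of -0.36 at 0 min. The tmRNA gene had a fitted log2 difference of 0.18 (SE 0.39, edgeR FDR = 0.751). Among the 265 genes with the lowest mean RPKM, 13 of 234 tested rose and 1 fell, with a median of 0.96, and the floor was 30.9 at 180 min.

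Of 2620 genes tested in GOX vs Control, 397 were called by edgeR, 145 higher and 252 lower, of which 86 and 44 changed at least 2-fold, and 626 by DESeq2. With total counts only, 161 were higher and 73 lower. The count was 0 without 30 min, 0 without 120 min and 262 without 180 min, against 939 and 626 genes at an unadjusted p under 0.05 in edgeR and called by DESeq2 with all times. It was 12, 155 and 139 without GOX at 30, 120 and 180 min, 165 and 144 without Control at 30 and 180 min, and 687 without GOX_AGXX at 180 min. All 4 named genes were lost without 30 min (edgeR adjusted p = 0.138, 0.138, 0.139 and 0.138) and without 120 min (0.0918, 0.0711, 0.143 and 0.115). SA2981_1908 was also lost without GOX at 30 min (0.0641). SA2981_1131 was lost without GOX at 30 (0.0977) and 120 min (0.0616) and without Control at 120 (0.0680) and 180 min (0.0586). SA2981_2502 was lost without GOX at 30 (0.0772), 120 (0.0572) and 180 min (0.0600), and without Control at 180 min (0.0705), where it was at -0.84. It was also lost with the floor subtracted (0.0598), where it was at -1.52, no smaller than in the main test. Without 180 min SA2981_2502 was at -0.93, still called. In the 11-gene region 0 genes rose without 30 min, 120 min, Control at 30 min or GOX at 30 min, 3 without 180 min, 1 without Control at 180 min, and 3 with log2 floor as a covariate. At 462291 to 465074, 0 genes fell without 30 min, 120 min or GOX at 30 min, and 1 fell with total counts only. After the 0 min difference was taken off, 0 genes were called by edgeR, and the medians of these regions were 1.71 and -0.38; SA2981_1908, SA2981_1893, SA2981_1131 and SA2981_2502 were at 2.29, 1.87, -1.11 and -0.98. With no time term these 4 were not called (edgeR adjusted p = 0.0939, 0.0519, 0.240 and 0.134), and with log2 floor as a covariate SA2981_1131 and SA2981_2502 were at -1.10 and -0.88, not called (0.144 and 0.123). With log2 floor as a covariate 174 genes were called, 46 with only the libraries of both treatments, and 9 with no time term. Among genes of at least 100 RPKM, scaled on those genes alone, 243 were called, 158 higher and 85 lower. The rescaling recentres changes, so these directions cannot be set against those of the main fit.

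GOX_AGXX vs Control asked what both coatings together did. In the 11-gene region at 2057231 to 2064700, 5 genes rose, with a median of 0.93; the median difference was 0.46, 1.09, 0.38 and 1.82 at the 4 times and -1.30 at 0 min. SA2981_1893 rose by 2.25 (SE 0.34, edgeR FDR = 0.00409) to 32.7 ± 7.11 CPM (SD over 4 times), and SA2981_1908 rose by 2.22 (SE 0.47, edgeR FDR = 0.0133) to 9977 ± 1968 CPM, with 0 min differences of 0.78 and 0.16. SA2981_1583 fell by 1.73 (SE 0.47, edgeR FDR = 0.0263) to 942 ± 521 CPM, and SA2981_2446 (2594686 to 2595174, minus strand) fell by 1.67 (SE 0.40, edgeR FDR = 0.0177), from 6001 ± 4364 to 2205 ± 1545 CPM; their 0 min differences were -1.36 and -1.15. With uncoated fibres SA2981_2446 was at 3099, 2560, 2163 and 1189 CPM at 30, 60, 120 and 180 min, below Control at each. SA2981_1893, SA2981_1908 and SA2981_1583 also lay on the same side of Control with uncoated fibres at these times. These shifts were thus not particular to the 2 coatings together. At 462291 to 465074, 3 of 4 genes fell, with a median of -0.67 and of -0.49 at 0 min. Among the 265 genes with the lowest mean RPKM, 35 of 234 tested rose and 1 fell, with a median of 1.24, and the floor was 44.3 at 180 min. The tmRNA gene had a fitted log2 difference of 0.07 (SE 0.39, edgeR FDR = 0.904).

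Of 2620 genes tested in GOX_AGXX vs Control, 418 were called by edgeR, 177 higher and 241 lower, of which 113 and 46 changed at least 2-fold, and 820 by DESeq2, with 1008 at an unadjusted p under 0.05 in edgeR. With total counts only, 173 were higher and 95 lower. The edgeR count was 216 without 60 min, 0 without 120 min and 116 without 180 min. It was 242, 634, 255 and 119 without Control at 30, 60, 120 and 180 min, and 712, 198, 70 and 53 without GOX_AGXX at those times. All 4 named genes were lost without 120 min (edgeR adjusted p = 0.102, 0.102, 0.163 and 0.120), and SA2981_1908, SA2981_1583 and SA2981_2446 without 180 min (0.0531, 0.0986 and 0.0606). SA2981_1583 was also lost without Control at 120 (0.0771) and 180 min (0.0743) and without GOX_AGXX at 60 (0.0518), 120 (0.0771) and 180 min (0.0953), without GOX and GOX_AGXX at 180 min (0.0729), and SA2981_2446 without GOX_AGXX at 120 (0.0640) and 180 min (0.0629). In the 11-gene region 0 genes rose without 60, 120 or 180 min, without Control at 30 or 180 min, or without GOX_AGXX at 60, 120 or 180 min, while 9 rose without Control at 120 min and 8 without GOX_AGXX at 30 min. At 462291 to 465074, 0 genes fell without 120 min and 1 fell with total counts only. With log2 floor as a covariate 2 genes were called, and 0 in either region; SA2981_1908, SA2981_1583 and SA2981_2446 were at 2.15, -0.79 and -1.08, not called (edgeR adjusted p = 0.0600, 0.241 and 0.144). With no time term the 4 named genes were not called (0.0516, 0.0973, 0.0973 and 0.167). After the 0 min difference was taken off 0 were called by edgeR, and the medians of these regions were 2.04 and -0.31; SA2981_1893, SA2981_1908, SA2981_1583 and SA2981_2446 were at 1.47, 2.07, -0.37 and -0.52. With only the libraries of both treatments 0 were called, and with no time term 8 were called. Without GOX and GOX_AGXX at 180 min 162 were called, of which 0 in the 11-gene region. Among genes of at least 100 RPKM, scaled on those genes alone, 243 were called, 135 higher and 108 lower. As with GOX, these directions cannot be set against those of the main fit.

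**Figure D4:**
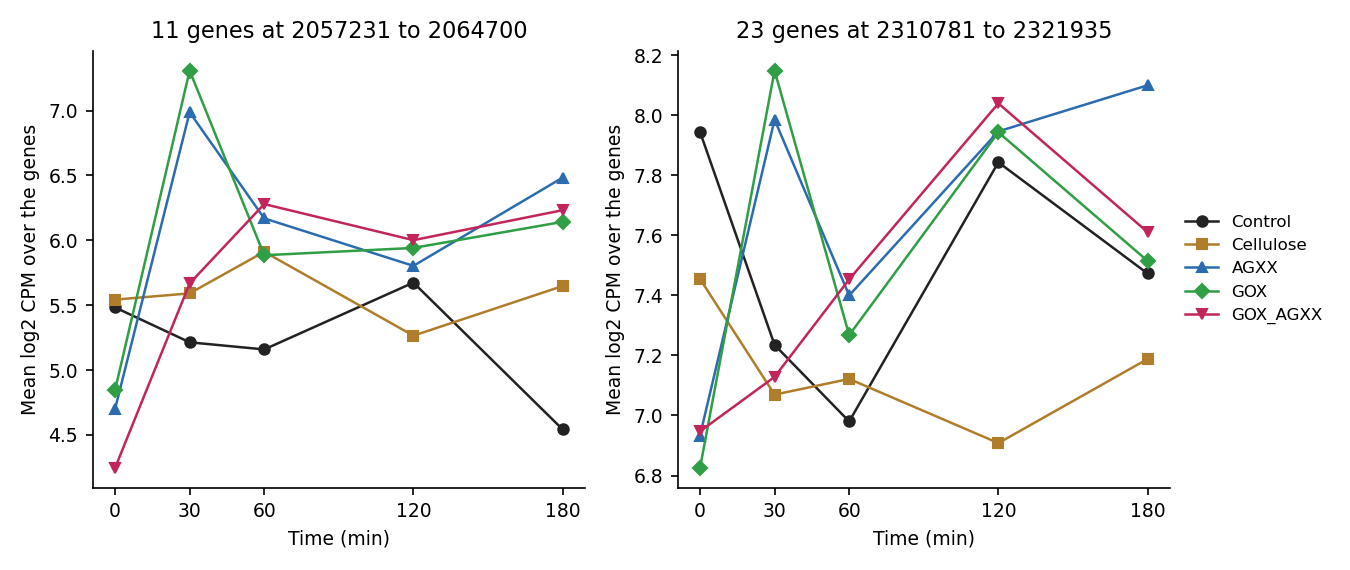
Mean log2 CPM of the 11-gene region (2057231 to 2064700) and the 23-gene region (2310781 to 2321935) against time in minutes, with 1 line per treatment and 1 library per point. At 30 min the 11-gene region lies above Control by a median of 1.81 with AGXX and 2.09 with GOX, and at 0 min the median differences are -0.86 and -0.65.

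Comparisons with Cellulose asked what a coating changed beyond the fibre. In the 23-gene region at 2310781 to 2321935 (minus strand) the median fitted log2 difference was 0.81 in AGXX vs Cellulose, 0.66 in GOX vs Cellulose and 0.54 in GOX_AGXX vs Cellulose, and 0.52, 0.39 and 0.30 with total counts only. For AGXX the median difference was 0.92, 0.27, 1.06 and 0.93 at 30, 60, 120 and 180 min, for GOX 1.12, 0.15, 1.001 and 0.35, and for GOX_AGXX 0.04, 0.32, 1.15 and 0.42; at 0 min it was -0.52, -0.65 and -0.47. The mean log2 CPM of the 23-gene region was 7.23, 6.98, 7.84 and 7.47 in Control at 30, 60, 120 and 180 min. With Cellulose it was 7.07, 7.12, 6.91 and 7.19, below Control except at 60 min. With AGXX it was 7.98, 7.40, 7.95 and 8.10, with GOX 8.15, 7.27, 7.94 and 7.51, and with GOX_AGXX 7.13, 7.45, 8.04 and 7.61. Part of the differences from Cellulose is thus its lower level than Control. The 11-gene region had medians of 0.78, 0.83 and 0.54 against Cellulose. SA2981_2494 (2645837 to 2648245, plus strand) was at 1442 ± 552 CPM with GOX_AGXX and 463 ± 53.5 with Cellulose (fitted log2 difference 1.49, SE 0.39, edgeR FDR = 0.349). The next gene, SA2981_2495 (2648656 to 2648862, plus strand), was at 2265 ± 771 and 673 ± 149 CPM (1.74, SE 0.38, edgeR FDR = 0.349). Both were higher at 4 of 4 times and also at 0 min, by 2.25 and 1.04, and less that difference they were at -0.81 and 0.64. Without 180 min both passed (edgeR adjusted p = 0.000196 and 0.00465), as they did without GOX and GOX_AGXX at 180 min (0.00718 and 0.00150); SA2981_2494 also passed without AGXX at 180 min (0.00167) and SA2981_2495 with DESeq2 (adjusted p = 0.0153). Against Control their fitted differences were 1.02 (edgeR FDR = 0.0706) and 0.49 (edgeR FDR = 0.335), of which the first passed without 180 min (adjusted p = 0.0217), without AGXX at 180 min (0.00744), among genes of at least 100 RPKM (0.0292) and with DESeq2 (0.0444). SA2981_2495 fell by 1.25 in Cellulose vs Control (SE 0.38, edgeR FDR = 0.0142), a call lost without 120 min (-0.68, adjusted p = 0.217), without Cellulose at 120 min (-1.09, 0.0709) and without Control at 120 min (-0.74, 0.106). It was also lost with total counts only (-0.73, 0.0832), with the floor subtracted (-0.76, 0.141), among genes of at least 100 RPKM (-0.75, 0.147), with no time term (-1.24, 0.0583), with log2 floor as a covariate (-0.02, 0.992) and less the 0 min difference (-0.59). The tmRNA gene had fitted differences of 0.57, 0.48 and 0.36 (edgeR FDR = 0.343, 0.494 and 0.656).

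With edgeR 0 of 2620 genes passed in AGXX vs Cellulose, where 760 had an unadjusted p under 0.05 and DESeq2 called 283 (173 higher, 110 lower). In GOX vs Cellulose edgeR called 0, with 581 at an unadjusted p under 0.05 and 34 called by DESeq2. In GOX_AGXX vs Cellulose edgeR called 0, with 341 and 3. Without 180 min the edgeR counts were 413, 647 and 491, of which 385, 481 and 465 were lower than with Cellulose. AGXX vs Cellulose gave 41 calls without GOX at 30 min, 91 without GOX at 180 min and 16 without GOX_AGXX at 30 min, and 894 with only its own libraries. GOX vs Cellulose gave 4 without Cellulose at 180 min and 250 without GOX at 180 min, and GOX_AGXX vs Cellulose gave 1 without AGXX at 180 min. Without GOX and GOX_AGXX at 180 min the counts were 779, 874 and 682. The 0 calls of the main fit thus rest on an error pooled over all treatments, and not only on how evenly these differences held. In the 23-gene region 0 genes passed in these comparisons. In AGXX vs Cellulose, 1 rose there without 180 min, 20 without GOX at 180 min, 18 without GOX at 30 min and 10 without GOX_AGXX at 30 min. In GOX vs Cellulose, 9 rose without 180 min and 20 without GOX at 180 min. Without GOX and GOX_AGXX at 180 min, 23, 23 and 9 rose.

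**Figure D5:**
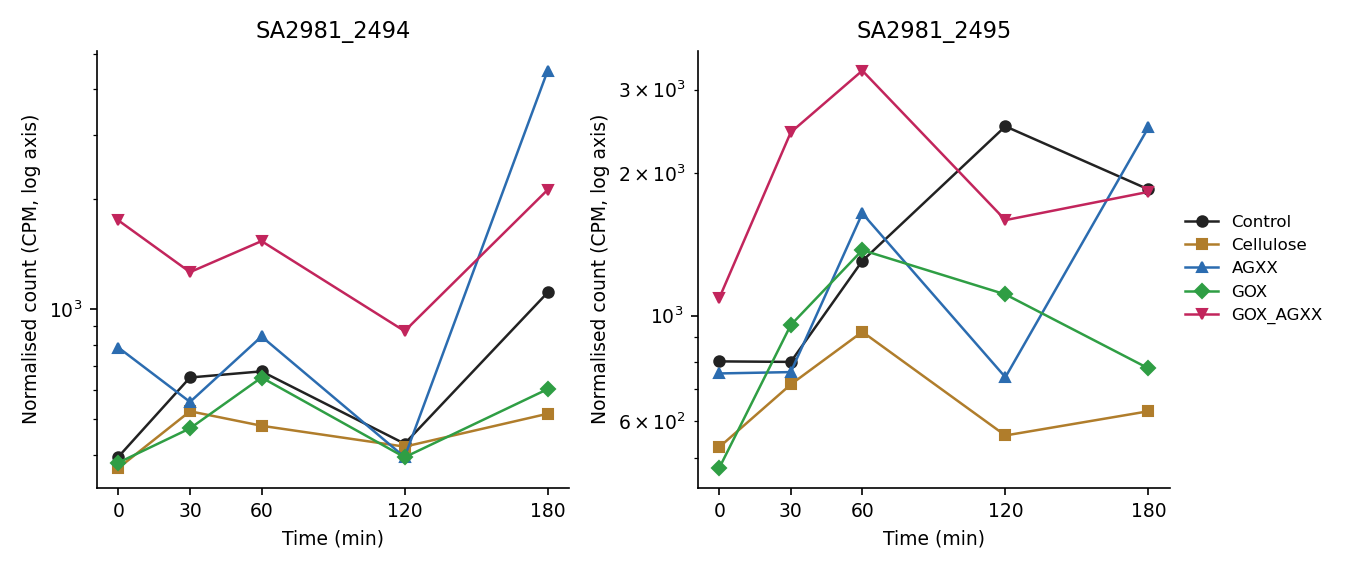
CPM of SA2981_2494 and SA2981_2495 (log axis) against time in minutes, with 1 line per treatment and 1 library per point. From 30 to 180 min GOX_AGXX averages 1442 and 2265 CPM and Cellulose 463 and 673; at 0 min SA2981_2494 is at 1750 CPM with GOX_AGXX and 395 in Control, and at 180 min at 4499 CPM with AGXX.

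GOX_AGXX vs AGXX asked what GOX added to AGXX. The 23-gene region had a median fitted log2 difference of -0.26, and the tmRNA gene one of -0.21 (edgeR FDR = 0.990). Called genes numbered 0 with edgeR, with 43 at an unadjusted p under 0.05 and 0 by DESeq2. The factorial interaction, GOX_AGXX - AGXX - GOX + Cellulose, asked whether the effect of both coatings differed from the sum of each alone on the log2 scale. With edgeR 0 of 2620 genes passed, with 553 at an unadjusted p under 0.05 and 1 by DESeq2. It was 202 without 180 min and 390 without GOX and GOX_AGXX at 180 min.

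Early against late effects of each kind of coated fibres against Control differed for few genes. Each is the effect at 120 and 180 min less that at 30 and 60 min. In early vs late AGXX vs Control, SA2981_0686 (756173 to 756757, minus strand) had a coefficient of 3.24 (SE 0.52, edgeR FDR = 0.0302). It was at 10.9, 18.0, 51.1 and 61.9 CPM with AGXX at 30, 60, 120 and 180 min and at 34.4, 28.9, 11.1 and 15.9 in Control. SA2981_0597 (667037 to 667597, plus strand) had one of -2.21 (SE 0.33, edgeR FDR = 0.0269), with 33.2, 48.7, 47.1 and 26.7 CPM under AGXX and 34.7, 55.3, 200 and 168 in Control. In early vs late GOX_AGXX vs Control, 10 genes had a negative coefficient and passed, and 0 passed with RLE scaling. Of these, SA2981_2416 (2557529 to 2557810, plus strand) had one of -2.30 (SE 0.39, edgeR FDR = 0.0496), with 297, 320, 527 and 175 CPM under GOX_AGXX and 227, 252, 1686 and 876 in Control. SA2981_1281 (1357866 to 1358456, plus strand) had one of -2.28 (SE 0.42, edgeR FDR = 0.0496), with 80.8, 94.3, 149.5 and 53.0 CPM under GOX_AGXX and 70.1, 91.9, 537 and 316 in Control. Uncoated fibres also lay below Control at 120 and 180 min for the named genes with a negative coefficient. With Cellulose SA2981_0597 was then at 59.9 and 49.8 CPM, SA2981_2416 at 531 and 429, and SA2981_1281 at 150 and 151. These differences were thus not particular to a coating. SA2981_0686 was at 20.9, 33.4, 19.3 and 31.1 CPM with Cellulose at 30, 60, 120 and 180 min.

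Of 2623 genes tested for early vs late effects, edgeR called 2 for AGXX vs Control (276 at an unadjusted p under 0.05, 29 by DESeq2), 0 for GOX vs Control (332 and 7) and 10 for GOX_AGXX vs Control (524 and 111). The AGXX count was 108 without 120 min, 50 without 180 min, 0 without 30 or 60 min, and 0 without AGXX or Control at 30, 60 or 180 min. It was 1 without AGXX at 120 min, GOX at 120 min, or GOX_AGXX at 30 or 60 min. It was 6 without Cellulose at 120 or 180 min or GOX_AGXX at 180 min, and 17 without Control or GOX_AGXX at 120 min. The GOX count was 536 without 120 min, 1 without 180 min and 5 without Control at 120 min. The GOX_AGXX count was 932 without 120 min, 27 without 180 min, 25 without Cellulose at 120 or at 180 min and 274 without GOX_AGXX at 120 min. It was 0 without 30 or 60 min, without any library at 30 or 60 min, and without Control or GOX_AGXX at 180 min. With total counts only, 1 gene with a positive and 0 with a negative coefficient were called for AGXX, and 0 and 1 for GOX_AGXX. With only the libraries of the compared treatments the count was 0 for both. With RLE scaling, with rRNA and tRNA kept, with log2 floor as a covariate, and without GOX and GOX_AGXX at 180 min it was 0 for GOX_AGXX, and among genes of at least 100 RPKM it was 22. For AGXX it was 12 with the floor subtracted, 12 with log2 floor as a covariate, 14 among genes of at least 100 RPKM and 5 without GOX and GOX_AGXX at 180 min.

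The contrast 180 min vs 0 min without coating asked what time did in Control and Cellulose cultures. SA2981_1366 (1452485 to 1453753, minus strand) rose by 4.04 (SE 0.34, edgeR FDR = 1.39e-05), from 140 to 2736 CPM in Control and from 119 to 1596 with Cellulose. SA2981_0330 (376485 to 376928, minus strand) rose by 3.70 (SE 0.40, edgeR FDR = 6.58e-05), from 3.64 to 68.2 CPM and from 10.6 to 91.4. SA2981_0241 (280456 to 281409, plus strand) fell by 3.71 (SE 0.37, edgeR FDR = 3.84e-05), from 13640 to 942 CPM and from 10780 to 911. SA2981_0771 (854009 to 854209, plus strand) fell by 3.25 (SE 0.39, edgeR FDR = 0.000134), from 11170 to 1412 CPM and from 7055 to 624. Of 2616 genes tested, edgeR called 395, 227 higher and 168 lower, of which 183 and 101 changed at least 2-fold, and DESeq2 called 546. With all 25 libraries the edgeR count was 810, 437 higher and 373 lower. It was 60 without Control at 0 min, 130 without Control at 180 min, 152 without Cellulose at 0 min, 606 without Control at 120 min and 609 without Cellulose at 120 min.

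Regions of adjoining genes were tested as lists with camera, 133 in each of 9 comparisons. With the preset correlation 31, 17, 18 and 21 regions were called in the 4 comparisons with Control, 36, 32 and 36 in those with Cellulose, 10 in GOX_AGXX vs AGXX and 33 in the factorial interaction, 234 in all. With the estimated correlation 0 were called. For the 11-gene region the camera adjusted p was 8.70e-06 in AGXX vs Control, 2.25e-05 in GOX vs Control and 0.00232 in GOX_AGXX vs Control, and the adjusted p was 0.755, 0.773 and 0.767 with an estimated correlation. For the 23-gene region it was 3.21e-14, 3.67e-12 and 1.43e-09 in the comparisons of AGXX, GOX and GOX_AGXX with Cellulose, and adjusted p = 0.672, 0.818 and 0.729 with an estimated correlation. With fry, which tests whether the genes of a region move one way without comparing them with other genes, 103 were called.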

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

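The tests of library depth, of the floor in the 11-gene region, and of the floor and the 0 min difference for SA2981_2494 and SA2981_2495 were chosen only after the result was seen, as was the setting with the floor subtracted.

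In groups of the 5 libraries of a treatment, the sample farthest from the rest was tested with Dixon's ratio in 90 groups, and 14 passed. Independent groups of replicates would give about 4.5. The 5 libraries are times and not replicates, many groups hold genes named for their differences, and some groups overlap. The 14 therefore do not show an excess of outlying libraries. The tmRNA share was 11.7% in AGXX at 0 min, and the tmRNA gene was at 96970 CPM there, against 25.4% to 29.9% and 272400 to 333500 CPM at later times. The rRNA share was 2.57% in GOX_AGXX at 180 min, against at most 0.903% in its other libraries. The floor was 5.92 in Control at 0 min, against at most 2.59 later, and 44.3 in GOX_AGXX at 180 min, against at most 8.79. SA2981_0234 was at 40.8 CPM in Control and 94.9 CPM in GOX_AGXX at 180 min, and SA2981_0398 at 100.8 CPM in GOX_AGXX at 180 min. In Control at 120 min SA2981_1317 was at 2330 CPM, SA2981_1583 at 7822 and SA2981_1138 at 1584, against at most 832, 2819 and 731 at the other times. SA2981_1893 was at 71.4 CPM in Cellulose at 0 min, SA2981_1131 at 2551 in AGXX at 60 min, and SA2981_2494 at 4499 in AGXX at 180 min.

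The effect against Control at 120 and 180 min differed from that at 30 and 60 min, by the test of the difference itself, for 2 genes with AGXX and 10 with GOX_AGXX. With AGXX the count was 0 without 30 min and 108 without 120 min, and with GOX_AGXX 0 without 30 min and 932 without 120 min; the other libraries and the settings that move these counts are given with the comparison above. With only the libraries of the compared treatments both counts were 0, and with RLE scaling, with rRNA and tRNA kept or with log2 floor as a covariate the GOX_AGXX count was 0.

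The 0 min libraries, which enter no treatment comparison, already differed from Control. SA2981_2494 was at 1750 CPM with GOX_AGXX at 0 min, against 395 in Control. At 0 min the floor was 17.1 with Cellulose, 13.1 with AGXX and 23.1 with GOX, against 5.92 in Control. Genes of rRNA, left out of the tests, took 2.12% of counts with GOX at 0 min, 2.23% with GOX at 180 min and 2.57% with GOX_AGXX at 180 min, against at most 0.778% in Control.

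Genes near the floor were higher with uncoated fibres than in Control. A read background spread evenly along the chromosome would put over 90% of the 265 genes with the lowest mean RPKM higher at 4 of 4 times, and 78.9% were; with the floor subtracted there were 151 rises against 462, a ratio of 32.7%, so it was neither excluded nor met in full. Genomic DNA carried into the libraries would give a ratio of reads near the origin to those near the terminus above 1.1, with a bootstrap interval above 1, in at least 6 of the 8 libraries with the highest floor, and 2 had one; 6 had an interval that included 1, which met the bound set beforehand for excluding DNA, but that bound was wrong, since 0 of those 6 intervals lay below 1.1 (ratios over the 8 libraries 1.04 to 1.21, interval bounds 0.872 to 1.38). In the libraries with a lower floor the ratio ran from 0.799 (Control at 120 min) to 1.16 (Control at 30 min). Most of these ratios were below 1, and each interval included 1. A ratio that is higher where the floor is higher is the direction genomic DNA would give, but that relation was not tested. Spearman's rho of floor and total counts was 0.347, short of the 0.5 that library depth would need, and Cellulose libraries were deeper than Control at 3 of 4 times. These explanations and an effect of the fibres on the cells cannot be told apart here. Reads were counted per gene without regard to strand, and each treatment and time has 1 library.

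The 11-gene region was higher with AGXX than in Control. An even read background was taken to put it lower with AGXX than with Cellulose, whose floor was higher at 4 of 4 times. The median log2 difference was 0.78 (0.53 to 0.98 over genes), above 0 in 11 of 11 genes. That prediction holds only near the floor, and the region had a mean RPKM of 122. Of the 10 groups of genes ordered by mean RPKM, groups 5 to 10 also had medians above 0, at 0.06 to 0.30. The region lay above these medians, but the sign alone does not decide against a background. With the floor subtracted 9 genes passed against Control with a median of 1.26. A difference already present at 0 min argues the wrong way: the median against Control was 1.19 (0.69 to 1.47 over genes) before and 1.83 (1.496 to 2.67) after that difference was taken off, above 0 in 11 of 11 genes, though 0 then passed edgeR because the 0 min library adds its own error (median SE 0.72). Reads shared with copies elsewhere and chance differences between single cultures were not tested, and a response to the coating may be among the explanations that stay open.

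SA2981_2494 and SA2981_2495 were higher with GOX_AGXX than with Cellulose at 4 of 4 times but did not pass edgeR. The floor gave at most 2.45% of their difference in RPKM, so reads added by a higher floor with GOX_AGXX were not its main source. At 30, 60 and 120 min the floor was lower with GOX_AGXX than with Cellulose, and the share was then 0 by the way it was computed. Whether a background in the Cellulose libraries lowered these genes there was not tested, so an even read background is not excluded. A difference between cultures at 0 min stays open: it was 59.8% of the fitted difference for SA2981_2495 and 151% for SA2981_2494, and after it was taken off the log2 differences were 0.64 (SE 0.82, edgeR FDR = 0.830) and -0.81 (SE 0.86, edgeR FDR = 0.767), so neither gene passed, and an effect of both coatings stays open too.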

How the results depend on the processing

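Settings chosen only after the data were seen were the floor subtracted, log2 floor as a covariate, genes of at least 100 RPKM, tmRNA left out, no GOX and GOX_AGXX libraries at 180 min, gaps of 50 bp and single libraries left out. For named genes against the main test, 1362 values kept their direction and side of the threshold or were uncalled in both (where a sign could change). Another 93 lost a call, 12 gained one and 2 changed sign, both less than 1 SE from no change. Region tests kept 917 and lost 75. Region medians kept 2692, moved 362 and reversed 5. Of the single-time values 16 kept and 4 moved. With RLE scaling, or rRNA and tRNA kept, early vs late GOX_AGXX vs Control gave 0 genes against 10. With total counts only, Cellulose, AGXX, GOX and GOX_AGXX vs Control gave 761, 314, 234 and 268 genes, and early vs late AGXX and GOX_AGXX 1 each; the median of all genes moved from -0.04 to 0.13, from -0.02 to 0.17 and from 0.03 to 0.23 with AGXX, GOX and GOX_AGXX. DESeq2 gave 626 for GOX vs Control, 820 for GOX_AGXX vs Control, 283, 34 and 3 for AGXX, GOX and GOX_AGXX vs Cellulose, 1 for the factorial interaction and 29, 7 and 111 for early vs late AGXX, GOX and GOX_AGXX. With only the libraries compared, AGXX, GOX and GOX_AGXX vs Control gave 266, 46 and 0, AGXX vs Cellulose 894, and early vs late AGXX and GOX_AGXX 0 each. With no time term Cellulose, AGXX, GOX and GOX_AGXX vs Control gave 208, 41, 9 and 8. Less the difference at 0 min these 4 gave 0 each with edgeR, a contrast that rests on 1 library per treatment at 0 min. All 25 libraries gave 810 genes for 180 min vs 0 min. With the floor subtracted Cellulose vs Control gave 244 and early vs late AGXX 12. With log2 floor as a covariate Cellulose, GOX and GOX_AGXX vs Control gave 0, 174 and 2, and early vs late AGXX and GOX_AGXX 12 and 0. That covariate can take up treatment differences of any cause, so its counts do not tell a background from a response. Among genes of at least 100 RPKM fewer genes are tested, and libraries are scaled on those genes alone. There Cellulose, GOX and GOX_AGXX vs Control gave 103, 243 and 243, of which 54, 158 and 135 were higher. Early vs late AGXX and GOX_AGXX gave 14 and 22 there. Without GOX and GOX_AGXX at 180 min, AGXX and GOX_AGXX vs Control gave 972 and 162, AGXX, GOX and GOX_AGXX vs Cellulose 779, 874 and 682, the factorial interaction 390, and early vs late AGXX and GOX_AGXX 5 and 0. Against 234 region calls, 0 were made with the estimated correlation, 103 with fry and 124 with the floor subtracted, with no overlap counted. Leaving out 1 time or library gave 0 to 1299 genes for Cellulose vs Control, 5 to 777 for AGXX vs Control, 0 to 687 for GOX vs Control, 0 to 712 for GOX_AGXX vs Control, 0 to 413, 0 to 647 and 0 to 491 for AGXX, GOX and GOX_AGXX vs Cellulose, 0 to 0 for GOX_AGXX vs AGXX, 0 to 202 for the factorial interaction, 0 to 108, 0 to 536 and 0 to 932 for early vs late AGXX, GOX and GOX_AGXX, 60 to 609 for 180 min vs 0 min, and 202 to 277 region calls. In Cellulose vs Control, SA2981_0398 was at -0.15 and the medians of 127897 to 139114 and 2784018 to 2790943 were at -0.14 and -0.14 with log2 floor as a covariate; SA2981_1583 was at 0.63 and the median of 2175118 to 2180463 at 0.0748 less the 0 min difference; and the medians of 166534 to 183102 and 1708375 to 1714255, which were -0.40 and -0.34 in the main test, were at 0.0229 and 0.11 with total counts only. Except where the setting itself leaves fewer genes or libraries, the cause was not tested. Depth limits weakly expressed genes most, and with 1 library per treatment and time the spread between cultures is unknown. Libraries were matched by time only, through the time term of the main test, and no replicate number pairs them.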

Other observations

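All tests in this part were chosen after the results were seen. The libraries of each comparison were split in other ways into groups of the same sizes and refitted, to ask whether chance can be excluded for the number of genes called by edgeR. For Cellulose vs Control 1 of 35 splits of the 8 libraries gave as many genes, the real one, with 1172 genes against at most 700 in another. For AGXX vs Control it was 1 of 35, with 485 against at most 237, and for GOX vs Control 1 of 35, with 397 against at most 1 (a share under 0.05 of all 35 splits). For GOX_AGXX vs Control 2 of 35 splits gave as many, and another split gave 500 genes against the real 418. For AGXX vs Cellulose, GOX vs Cellulose and GOX_AGXX vs AGXX the real count was 0, with at most 0 in another split, and for GOX_AGXX vs Cellulose it was 0, with at most 337 in another. For the factorial interaction it was 0, with at most 233 in another of 100 splits of the 16 libraries. Any split gives at least 0 genes, so for these 5 comparisons the tally of 35 of 35 or 100 of 100 splits was fixed beforehand and says nothing of chance. A split that calls 337 or 233 genes where the real one calls 0 points to a structure of the samples; what those splits separate was not tested. The libraries are matched by time, and of the 35 splits 8 put 1 library of each time in each group. In each of the 4 comparisons with Control the real split was the 1 of these 8 with as many genes, and 8 splits are too few for a share under 0.05.

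Regions called by camera with the preset correlation reached the real count in more than 0.05 of the splits, so chance cannot be excluded for their number. As many as the real count were found in 8 of 35 splits for Cellulose vs Control (31 regions, a median of 21 and at most 53 in the other splits), 18 for AGXX vs Control (17, a median of 16.5, at most 52), 17 for GOX vs Control (18, a median of 16.5, at most 35) and 9 for GOX_AGXX vs Control (21, a median of 14.5, at most 39). They were found in 6 of 35 splits for AGXX vs Cellulose (36, a median of 25.5, at most 42), 6 for GOX vs Cellulose (32, a median of 21.5, at most 49), 2 for GOX_AGXX vs Cellulose (36, a median of 24.5, at most 40), 34 for GOX_AGXX vs AGXX (10, a median of 24, at most 34), and 19 of 100 for the factorial interaction (33, a median of 24, at most 45).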
